A study of Mus musculus with 2 samples.

How the data were processed

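Total RNA was measured in the left cerebral cortex of 2 female B6CASTF1/J mice aged 2 months, per the labels, 1 stranded library per replicate. The labels number the tissue samples separately and give both the same donor entry; they are called biological replicates 1 and 2 there and are read here as 2 animals, which no label states in words. RNA was purified with a column kit for animal tissue, per the labels' protocols, and the starting amount was 300 ng. The labels name a spike-in profile for stranded, ribosome-reduced libraries.

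For each library the authors deposited 3 tables, all on assembly mm10 with GENCODE M21, per the list of files that came with each library. Expected counts and TPM per gene and per transcript were deposited in tables derived from alignments to the transcriptome, called alignment-based here. A further deposited table holds estimated counts and TPM per transcript, derived from the reads and an index without those alignments, called read-based here. The aligner and both quantification tools are not given in the sources used here. Length minus effective length of long transcripts, from the deposited effective length columns, was 99 bases in the alignment-based tables and 340.1 and 342.1 bases in the read-based ones. TPM as deposited has a fixed sum over all features of a table, spike-ins included, so a few abundant short RNAs lower the TPM of all other genes. The reference genome is that of C57BL/6J, and reads from CAST/EiJ alleles were quantified against it, which can lower counts of genes with many differences.

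The alignment-based gene table holds 81881 features: 55536 annotated genes, all found in the GENCODE M21 annotation, 96 spike-ins, 1 phage control and 26248 transfer RNA features. The total of expected counts was 31196858 in replicate 1 and 32292150 in replicate 2 (31815645 and 32923189 in the read-based tables), of which spike-ins took 0.372% and 0.363%. For 86 genes the read-based tables hold no transcript. Transfer RNA features, spike-ins and the phage control stayed out of gene counts and scaling. Read-based gene values are sums over transcripts. The gene coordinates and biotypes come from GENCODE M21.

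Expected counts were rounded to whole numbers. The libraries were scaled with TMM in edgeR 4.0.16 (R 4.3.3) over genes with a mean count of at least 10, which set replicate 2 to 1.01 times the size of replicate 1. The log2 ratio of replicate 2 over replicate 1 used a prior count of 0.5 and an exact Clopper-Pearson 95% interval from the 2 counts. A gene was called different when its mean count was at least 10 and the interval lay wholly beyond 2-fold. PCR reads without molecular identifiers are not independent molecules, so intervals and floors cover counting error only. The edgeR common dispersion was fitted with an intercept alone, and a chi-square test of the counts over genes compared the libraries. With 1 group, no test between groups was made and no p-value is printed.

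41 gene lists with 432 genes were fixed before the data were examined: cell classes, other tissues that a dissection could carry, cortical layers, cell states, neurotransmission, sex-chromosome checks, RNA classes and isoforms. All genes matched, 1 of them through an older symbol in RefSeq. A list's median log2 ratio over members with a mean count of at least 10 was set against 10000 random lists of the same size, drawn from 20 bins of mean count with a fixed seed; lists with fewer than 3 such members got no percentile. The named genes follow a rule fixed before the data were examined: the 10 nuclear genes of highest mean TPM; the 3 highest members and the lowest of each list, and all members of the sex-chromosome checks; up to 10 called genes per direction with a mean count of at least 100; up to 5 members of largest ratio in each list outside the 2.5th and 97.5th percentiles; and, of the isoform list, the 8 most abundant genes and those whose leading transcript differed between quantifications. Genes named outside it are said to have been chosen after their values were seen, and some genes that the rule takes in are not reported here. Near-identical copies were found with blastn 2.17.0 among annotated transcripts, at 98% identity or more over at least 80% of the shorter transcript.

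The interval rule and the dispersion were tested on simulated data. Changed genes were drawn only at a mean count of at least 100, and no reads were shared between copies. How often the rule finds changed genes below that count, or errs among near-identical copies, was therefore not tested. In 2 libraries simulated at the observed means of 18562 genes with a biological coefficient of variation of 5%, edgeR recovered 5.01% over unchanged genes. In that simulated comparison of replicate 2 with replicate 1, the interval rule called 0 of 18362 unchanged genes, 4 of 50 changed by 2-fold, which is the limit itself, 48 of 50 changed by 3-fold and all 50 and 50 changed by 4-fold and 8-fold. Alternatives covered the scaling (DESeq2 1.42.0 size factors, total count, spike-ins), count and TPM minimums, the pseudocount, the fold limit, the read-based tables, TPM over fewer features and each replicate alone. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 was used for all other steps.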

Results

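Total RNA was sequenced from the left cerebral cortex of 2-month-old female B6CASTF1/J mice, the first-generation hybrid of C57BL/6J and CAST/EiJ parents. The series held 1 group with 2 biological replicates, 1 library each, and both libraries were made from 300 ng of RNA with ERCC spike-ins, synthetic RNAs added in known amounts. Replicate 1 carried 31196858 and replicate 2 32292150 expected counts. The labels number 2 separate tissue samples but give them the same donor entry, so the replicates are read as 2 animals without a label that says so, and their spread may be technical. With no second condition, the data answered which genes, transcripts and RNA classes were present and at what level, and where the cortex of the 2 replicates differed. Levels are given as TPM, a length-corrected share of all transcripts, from the alignment-based gene tables, as mean ± SD over n = 2 libraries. A difference between the replicates compares these 2 libraries and has no replicate check of its own, so its 95% intervals cover counting error only and no p-value is given. At these depths 3 counts, the limit that a count of 0 allows, corresponded to 0.163 TPM in replicate 1 and 0.152 TPM in replicate 2 for a transcript of 1 kb.

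Female-specific Xist was abundant and Y-linked genes were at 5 counts or fewer, which matches the female labels. Xist, the RNA that coats the inactive X chromosome (ENSMUSG00000086503.4, chromosome X, 103460366 to 103483254, minus strand, mm10), stood at 75 TPM in replicate 1 and 78.1 TPM in replicate 2. The X-linked genes Ddx3x, Eif2s3x, Kdm5c and Kdm6a, which escape X inactivation, had levels of 87.5 ± 8.65, 64.5 ± 1.12, 29 ± 2.26 and 20.7 ± 0.339 TPM, and Tsix, the antisense partner of Xist, 0.33 ± 0.127 TPM. Of the 4 Y-linked genes, Eif2s3y and Ddx3y had 0 counts in both libraries, Uty had 1 and 2 counts and Kdm5d 5 and 0 counts in replicates 1 and 2.

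Small structural RNAs led the abundance ranking. The 7SL RNA genes Rn7s1 and Rn7s2, which encode the RNA of the signal recognition particle, had the highest mean level of all nuclear genes. They are near-identical copies with the same value in each library, 140347 ± 4287 TPM each, so their reads cannot be assigned to 1 gene, and together they took 28.1% ± 0.857 of all TPM. Rn7sk, the 7SK RNA that holds back transcription elongation, followed at 59914 ± 4174 TPM. The other nuclear genes among the 10 highest were Gm26917 (12999.9 ± 396 TPM), the RNase P RNA Rpph1 (7216 ± 25.9 TPM), Malat1 (5892 ± 235 TPM), the RNase MRP RNA Rmrp (3203 ± 118 TPM), and the chromosome 1 pseudogenes of mitochondrial genes Gm28661 (6518 ± 184 TPM), Gm10925 (5819.7 ± 1007 TPM) and Gm28437 (4390.0 ± 444 TPM). Reads of these pseudogenes cannot be told from those of mt-Co2, mt-Atp6 and mt-Co3, which held 1.91%, 30.2% and 26.6% of the summed counts of gene and pseudogene. Nuclear protein-coding genes took 45.4% ± 1.82 of TPM but 80.7% ± 0.651 of expected counts, because TPM divides by length and weights short RNAs up. The highest nuclear protein-coding genes, which were listed after their values were seen, were Snap25 (1327 ± 30.2 TPM), Camk2a (1138 ± 37.8 TPM), Hspa8 (1042 ± 35.4 TPM), Gapdh (1042 ± 74.8 TPM) and Snurf (1039 ± 45 TPM); Snurf shares its locus with Snrpn, so its count is uncertain.

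Mitochondrial ribosomal RNA held 6.35% ± 0.0337 of TPM and genes of the nuclear rRNA biotype 0.00318% ± 0.0000481. The biotype is no measure of all nuclear ribosomal RNA, since Gm26917, annotated as long intergenic, lies beside an annotated rRNA gene on chromosome 17 and its reads enter the long intergenic class. As a share of expected counts, mitochondrial ribosomal RNA was 5.09% in replicate 1 (exact Clopper-Pearson 95% interval 5.08 to 5.09) and 5.26% in replicate 2 (5.25 to 5.26). Mitochondrial mRNAs took 2.57% ± 0.0304, long intergenic RNAs 3.05% ± 0.00476, pseudogenes 3.23% ± 0.0952, small nuclear RNAs 1.92% ± 0.361 and spike-ins 0.705% ± 0.0272 of TPM. Reads split between mitochondrial genes and pseudogenes enter these shares: summed with 4 chromosome 1 pseudogenes, a sum chosen after the values were seen, mitochondrial mRNAs took 4.49% ± 0.173 of TPM, and the other pseudogenes 1.3% ± 0.0478. The 10 highest genes of each library, mitochondrial genes included, summed to 44.3% ± 1.35 of TPM. The second quantification, made from the reads without the genome alignment, placed 0.00487% ± 0.000404 of TPM in the class of 7SL and 7SK against 34.1% ± 1.28 in the alignment-based tables, and 76% ± 0.706 in nuclear protein-coding genes. Levels in TPM are therefore on different scales in the 2 kinds of table. The class of 7SL and 7SK held 33.2% of TPM in replicate 1 and 35% in replicate 2, which lowers the TPM of the other genes in replicate 2. Ratios between the replicates were therefore taken from scaled counts and not from TPM.

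**Figure D1:**
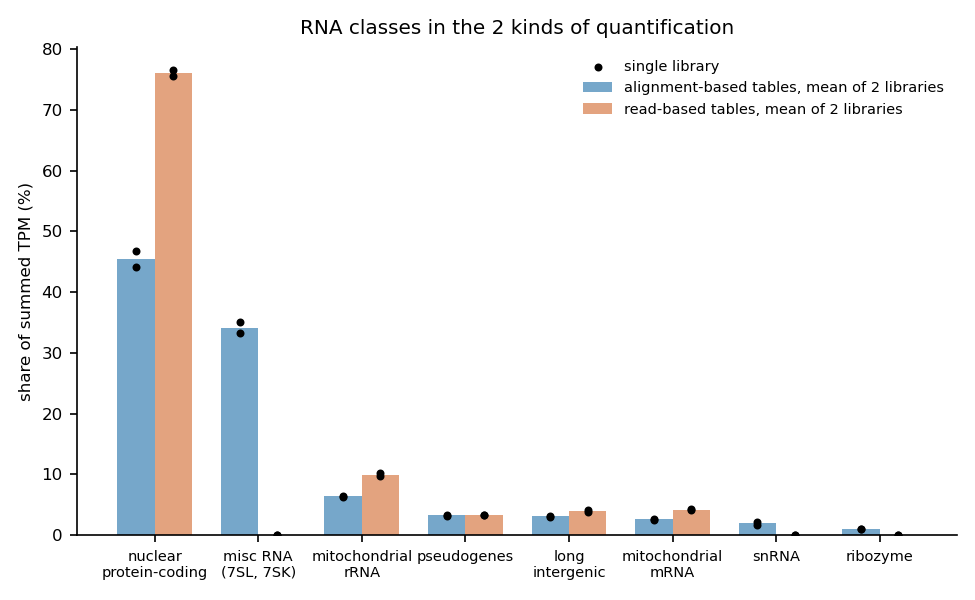
Share of summed TPM (vertical axis, percent) taken by 8 RNA classes in the alignment-based and the read-based tables; bars are means of 2 libraries and points are single libraries. Nuclear protein-coding genes hold 45.4% in the alignment-based and 76% in the read-based tables.

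Of 55536 annotated genes, 15259 reached 1 TPM in both libraries, among them 12958 of 22028 protein-coding genes (58.8%), 299 of 5854 long intergenic RNAs and 89 of 1507 small nucleolar RNAs. 8509 genes reached 10 TPM and 968 reached 100 TPM in both, while 1118 passed 1 TPM in 1 library only. Across the 15259 detected genes, log2(TPM + 1) correlated between the replicates with Pearson's r = 0.994 and Spearman's rho = 0.993; genes are not independent replicates, so no p is given. The common biological coefficient of variation, the spread beyond counting noise estimated by edgeR, was 4.08% over 18562 genes. The counts of the 2 libraries differed by more than sampling noise, with a chi-square of 65202 on 12842 degrees of freedom. Separate libraries of 1 RNA can exceed counting noise too, so this does not show that 2 animals were sampled. Among 12843 genes with a mean count of at least 100, 99.5% lay within 1.5-fold of equality.

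The pan-neuronal list stood highest among the 9 cell class lists. It had medians of 241 and 230.1 TPM in replicates 1 and 2, led by Snap25 (1327 ± 30.2 TPM), a SNARE protein of vesicle fusion (ENSMUSG00000027273.13, chromosome 2, 136713453 to 136782428, plus strand), the calcium sensor Syt1 (515 ± 15.1 TPM) and the microtubule protein Map2 (484 ± 1.82 TPM); Nefm was lowest at 76.3 ± 1.7 TPM. Genes of excitatory neurons had medians of 54.7 and 49.4 TPM, led by the kinase subunit Camk2a (1138 ± 37.8 TPM) (ENSMUSG00000024617.16, chromosome 18, 60925618 to 60988152, plus strand), Nrgn (822 ± 17.1 TPM) and the vesicular glutamate transporter Slc17a7 (549.5 ± 18 TPM), with Neurod1 lowest at 7.95 ± 0.742 TPM. Genes of inhibitory neurons had medians of 42.9 and 41.3 TPM, led by Sst (189 ± 1.82 TPM), the GABA-synthesising enzyme Gad1 (179 ± 4.65 TPM) and Lamp5 (119 ± 11.3 TPM), and Htr3a was lowest at 3.21 ± 0.12 TPM. All 12, 11 and 13 members of these lists reached 1 TPM in both libraries.

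Glial and vascular markers covered a wide range. The astrocyte list had medians of 53.6 and 50.7 TPM, with the glutamate transporters Slc1a2 (719.8 ± 14.2 TPM) and Slc1a3 (126 ± 0.262 TPM) and the glycolytic enzyme Aldoc (348 ± 6.08 TPM) on top and Aldh1l1 lowest at 28.7 ± 0.658 TPM. Oligodendrocyte genes had medians of 27.8 and 29 TPM, with the myelin genes Mbp (319 ± 22.3 TPM) and Mobp (88.7 ± 4.14 TPM) among the highest, and reached down to Opalin (2.85 ± 0.594 TPM). Microglial genes had medians of 17.5 and 16.1 TPM, with Csf1r (30.7 ± 0.233 TPM) and C1qb (25.4 ± 0.559 TPM) among the highest and Trem2 (4.38 ± 0.46 TPM) lowest. Endothelial genes had medians of 9.05 and 8.51 TPM, from Ly6c1 (31.9 ± 0.325 TPM), Itm2a (18.4 ± 0.962 TPM) and the VEGF receptor Flt1 (16.2 ± 0.00707 TPM) to Kdr (2.19 ± 0.304 TPM). Oligodendrocyte precursor genes had medians of 7.43 and 7.25 TPM, from Olig1 (35.9 ± 0.474 TPM), Pdgfra (17.4 ± 0.523 TPM) and Gpr17 (12.3 ± 0.643 TPM) to Enpp6 (1.82 ± 0.12 TPM). Mural genes had the lowest medians, 4.61 and 3.58 TPM, from Vtn (31.7 ± 2.88 TPM), Rgs5 (18.1 ± 0.0424 TPM) and Acta2 (5.89 ± 1.59 TPM) to Kcnj8 (1 ± 0.0495 TPM), and 9 of 10 members were detected. The astrocyte and excitatory medians changed places between the libraries, so their order was within the replicate spread, and the other 7 lists held the same place in both. A list median depends on the markers chosen and counts no cells.

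**Figure D2:**
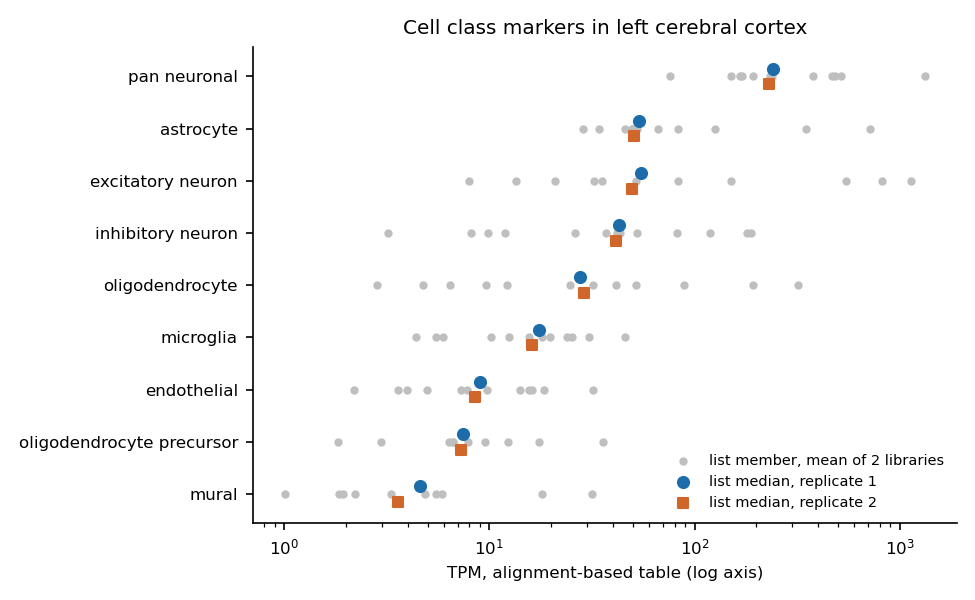
TPM from the alignment-based tables (horizontal log axis) for the 9 cell class lists; grey points are list members as means of 2 libraries, circles and squares the list medians in replicates 1 and 2. The pan-neuronal medians lie at 241 and 230.1 TPM and the mural medians at 4.61 and 3.58 TPM.

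Markers of the cortical layers were present throughout. Upper-layer genes (layer 2/3) had medians of 62.6 and 58.1 TPM, led by Rasgrf2 (104 ± 6.77 TPM), Cux2 (96.4 ± 6.58 TPM) and Calb1 (71 ± 2.93 TPM) and lowest at Otof (12.6 ± 1.2 TPM). Layer 4 genes had medians of 26.2 and 22.9 TPM, from Kcnh5 (37.3 ± 2.17 TPM), Rorb (24.7 ± 2.55 TPM) and Whrn (24.6 ± 2.31 TPM) to Scnn1a (1.29 ± 0.297 TPM). Layer 5 genes had medians of 16.8 and 16 TPM, from Bcl11b (30.2 ± 0.933 TPM), Etv1 (28.6 ± 4.58 TPM) and Tshz2 (18.5 ± 3.1 TPM) to Qrfpr (2.31 ± 0.438 TPM), and layer 6 and subplate genes 6.94 and 5.46 TPM, from Crym (35.8 ± 1.82 TPM), Rprm (32.2 ± 2.65 TPM) and Tle4 (16.2 ± 1.12 TPM) to Nxph4 (2.9 ± 0.82 TPM). All members of the 4 layer lists reached 1 TPM in both libraries.

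Markers of tissue next to the cortex were mostly low, with blood and striatal genes as exceptions. Red blood cell genes had medians of 58.1 and 72 TPM, with the globins Hba-a1 (129.8 ± 23.6 TPM), Hbb-bs (129.8 ± 21.8 TPM) and Hba-a2 (115 ± 19.1 TPM) and with Slc4a1 (0.07 ± 0 TPM) lowest. Genes of striatal projection neurons had medians of 25.3 and 16.9 TPM, led by Ppp1r1b (99.6 ± 15.3 TPM), Penk (87.5 ± 16.3 TPM) and Pde10a (53.1 ± 6.95 TPM), genes that cortical cells express as well, with Ido1 (0.31 ± 0.0849 TPM) lowest. Fibroblast and meningeal genes had medians of 6.93 and 5.66 TPM, led by Igf2 (38.2 ± 13.2 TPM), Dcn (9.87 ± 1.19 TPM) and Slc6a13 (9.72 ± 2.55 TPM), with Lum (0.86 ± 0.113 TPM) lowest. Thalamic genes had medians of 4.8 and 4.66 TPM with Slc17a6 (13.1 ± 1.44 TPM), Ramp3 (6.25 ± 0.983 TPM) and Prkcd (6.03 ± 1.2 TPM) on top and Gbx2 (0.205 ± 0.0495 TPM) lowest. Olfactory bulb genes had medians of 1.69 and 2.53 TPM, with Calb2 (10.2 ± 1.81 TPM), Cdhr1 (6.5 ± 0.629 TPM) and Trh (4.59 ± 1.36 TPM) on top and S100a5 at 0 counts in both libraries. Hippocampal genes had medians of 1.02 and 1.16 TPM, led by Fibcd1 (4.42 ± 0.643 TPM), Prox1 (3.46 ± 0.445 TPM) and C1ql2 (1.99 ± 0.29 TPM), with Dsp (0.025 ± 0.00707 TPM) lowest. Choroid plexus genes had medians of 0.64 and 0.84 TPM, with Ttr (20.2 ± 19.9 TPM), Kl (1.7 ± 0.163 TPM) and Clic6 (1.06 ± 0.0849 TPM) on top and Kcne2 (0.06 ± 0.0424 TPM) lowest, and ependymal genes 0.54 and 0.995 TPM, with Rarres2 (5.88 ± 0.594 TPM), Foxj1 (1.77 ± 0.148 TPM) and Dynlrb2 (0.995 ± 0.757 TPM) on top and Pifo (0.145 ± 0.0495 TPM) lowest. Of these, 3 of 9 choroid plexus, 2 of 6 ependymal and 4 of 8 hippocampal members reached 1 TPM in both libraries.

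Receptor and synaptic genes showed which subunits were most abundant. Among glutamate receptor genes the AMPA subunit Gria2 (235 ± 8.01 TPM) and the NMDA subunits Grin1 (204 ± 12.6 TPM) and Grin2b (127 ± 1.8 TPM) stood highest and Grin2d lowest at 5.85 ± 0.636 TPM. Among GABA receptor genes the metabotropic subunits Gabbr1 (316 ± 11.2 TPM) and Gabbr2 (109.8 ± 1.02 TPM) were among the highest, and Gabra6 was near 0 at 0.03 ± 0.0424 TPM. Presynaptic genes were led by the vesicle proteins Syp (780.2 ± 47.6 TPM) and Vamp2 (484 ± 9.93 TPM), with Pclo lowest at 68.7 ± 1.34 TPM. Postsynaptic genes were led by the scaffold proteins Dlg4 (379.6 ± 7.64 TPM) and Shank1 (293 ± 12.4 TPM) and the kinase subunit Camk2b (287 ± 16.3 TPM), with Nlgn1 lowest at 47.1 ± 1.51 TPM. Neuropeptide precursors ranged from Cck (305 ± 1.32 TPM), Sst (189 ± 1.82 TPM) and Penk (87.5 ± 16.3 TPM) to Nts (5.93 ± 1.36 TPM). Receptors for monoamines, acetylcholine, cannabinoids and opioids were led by the muscarinic receptor Chrm1 (66.5 ± 2.15 TPM), the cannabinoid receptor Cnr1 (51.6 ± 3.13 TPM) and Chrm4 (27.3 ± 2.43 TPM), with Oprk1 lowest at 2.75 ± 0.46 TPM. The list medians were 72.7 and 69.9 TPM, 44.2 and 41.4 TPM, 201 and 190.3 TPM, 147 and 148 TPM, 22.3 and 20.6 TPM and 11.1 and 11.5 TPM in that order. Of the 18 leading members of these 6 lists, 16 led in the read-based tables too.

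Genes of cell state differed widely in level. Immediate early genes, which neuronal activity induces within minutes, had medians of 43.1 and 33 TPM, led by Arc (224 ± 10.3 TPM), Egr1 (177 ± 27.8 TPM) and Nr4a1 (101 ± 16 TPM), with Ier2 at 7.9 ± 0.594 TPM. Later activity-regulated genes had medians of 24.3 and 22.6 TPM, from Homer1 (201 ± 3.9 TPM), Scg2 (106 ± 4.96 TPM) and Nptx2 (53.4 ± 0.198 TPM) to Inhba (8.14 ± 2.03 TPM). Glucocorticoid-responsive genes had medians of 35.5 and 37.6 TPM, from the metallothioneins Mt1 (223 ± 8.29 TPM) and Mt2 (176 ± 6.72 TPM) and the kinase Sgk1 (60.5 ± 3.97 TPM) to Plin4 (2.13 ± 0.0141 TPM). Clock genes and outputs had medians of 27.3 and 25 TPM, from Tef (100.1 ± 3.95 TPM), Per1 (84.3 ± 7.43 TPM) and Cry2 (57.9 ± 3.94 TPM) to Ciart (7.24 ± 0.629 TPM), and heat shock genes 54.6 and 50.6 TPM, from Hspa8 (1042 ± 35.4 TPM), Hsp90aa1 (451 ± 37.4 TPM) and Hsph1 (159.7 ± 4.69 TPM) to Hspa1a (7 ± 0.523 TPM). Sterol synthesis genes had medians of 29.2 and 27.7 TPM, with Hmgcs1 (106 ± 4.83 TPM) highest. Interferon-stimulated genes were low, with medians of 1.06 and 0.69 TPM, with Ifi27 (30.6 ± 0.905 TPM) and Ifit3 (2.21 ± 0.297 TPM) among the highest and Ifi44 (0.055 ± 0.0778 TPM) lowest. Genes of cell division and immature neurons had medians of 0.33 and 0.43 TPM, from Dcx (9.68 ± 0.976 TPM), Sox11 (8.44 ± 0.0849 TPM) and Cd24a (3.46 ± 0.7 TPM) to Mki67 (0.2 ± 0.0707 TPM).

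Imprinted genes, which are expressed from 1 parental allele in at least some tissues or transcripts, had medians of 32.6 and 31.2 TPM. Of these genes, 23 of 24 reached 1 TPM in both libraries. The noncoding RNA Meg3 (1471 ± 15.6 TPM), Snurf (1039 ± 45 TPM) and Gnas (797 ± 5.95 TPM) led and H19 was lowest at 0.345 ± 0.191 TPM. The tables hold no allele counts, so parental origin was not analysed here. Long noncoding RNAs were led by Malat1 (5892 ± 235 TPM), a nuclear speckle RNA, Snhg11 (384 ± 18.5 TPM) and Miat (109 ± 5.3 TPM), and reached down to Sox2ot (10.4 ± 0.205 TPM), with list medians of 72.7 and 65.5 TPM. Mitochondrial mRNAs were led by mt-Co1 (5735 ± 164 TPM), mt-Cytb (3038 ± 149.98 TPM) and mt-Nd1 (2937 ± 47.2 TPM), with list medians of 1663 and 1904 TPM. That order depends on how reads were split, since the near-identical pseudogenes of mt-Co2, mt-Atp6 and mt-Co3 held 6518, 5820 and 4390 TPM. Each of these values lies above mt-Cytb and mt-Nd1. mt-Co2 was lowest at 126 ± 8.7 TPM and is uncertain. Its near-identical pseudogene Gm28661 held 75979 and 84706 counts in replicates 1 and 2 against 1583 and 1539 on mt-Co2 itself.

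Isoform shares, the part of a gene's transcript TPM held by 1 annotated transcript, were compared for 28 genes with known brain isoforms. The same transcript led in both libraries for 28 of the 28 genes in the alignment-based tables, and it held more than 50% of the gene in 19 of them. Among the most abundant of these genes, App-201 held 91.8% ± 0.747 of the amyloid precursor gene, Snap25-201 held 84.8% ± 1.61 and Camk2a-203 held 66.2% ± 2.26 of their genes, all as mean ± SD with n = 2. Dlg4-203 held 54.8% ± 1.74, Pkm-202 held 50.1% ± 2.27, Dnm1-201 held 47.2% ± 0.0443 and Map2-204 held 41.8% ± 0.153. The read-based tables named the same leading transcript for 25 of the 28 genes and another for Pkm, Syn1 and Grin1. For the pyruvate kinase gene Pkm, Pkm-201 led there with 47.7% ± 3.32. For the synapsin gene Syn1, Syn1-201 held 60.9% ± 1.06 in the alignment-based tables, whereas Syn1-202 held 66.6% ± 1.42 in the read-based ones. For the NMDA receptor gene Grin1, Grin1-201 held 38.2% ± 4.65 and Grin1-205 28% ± 0.62, respectively. The leading share of Dlg4-203 was 29.8% ± 2.13 in the read-based tables, so the kind of quantification moved it by more than the replicate spread.

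**Figure D3:**
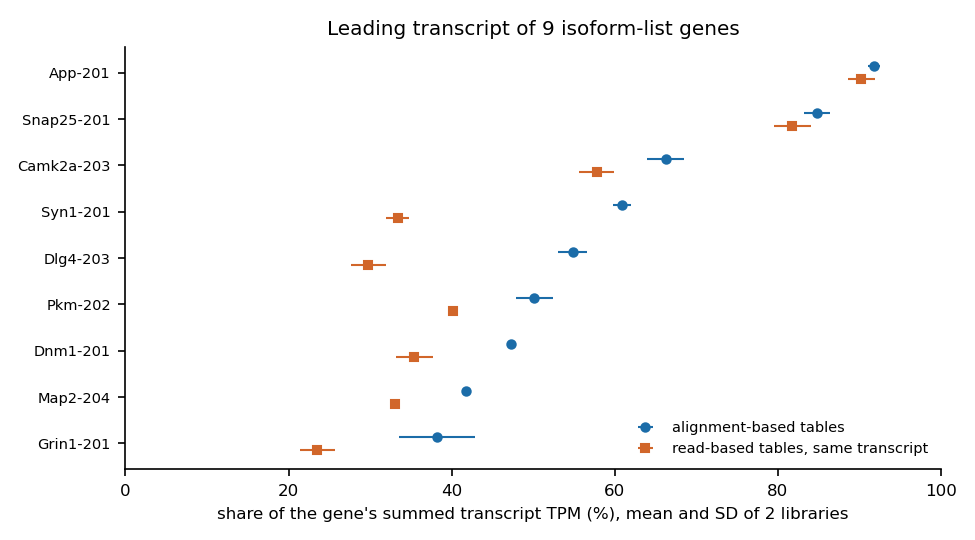
Share of each gene's summed transcript TPM (horizontal axis, percent) held by its leading transcript in the alignment-based tables, for 9 genes named in the text, with the share of the same transcript in the read-based tables; points are means and bars SD of 2 libraries. App-201 is highest at 91.8% and Grin1-201 lowest at 38.2%.

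Ttr was higher in replicate 2. This gene, which encodes transthyretin, a thyroid hormone carrier abundant in choroid plexus (ENSMUSG00000061808.4, chromosome 18, 20665280 to 20674321, plus strand), had 136 and 816 counts in replicates 1 and 2, a log2 ratio of 2.56 (95% interval 2.30 to 2.84) for replicate 2 over replicate 1. In all, 57 of 18562 genes with a mean count of at least 10 had a 95% interval wholly beyond 2-fold, 29 higher and 28 lower in replicate 2; 25 were pseudogenes. The other 11 called genes with a mean count of at least 100 each had a near-identical copy in the annotation, so their counts are uncertain. Rpl7a-ps11 had 791 and 0 counts, 268-fold lower against a floor of 3 counts in 1 library, and its copy Gm8226 had 10 and 810 counts. Among pseudogene copies of Gapdh, Gm13394 had 0 and 548 counts, 180.01-fold higher against that floor, and Gm14760 had 202 and 527 counts. Gm5559 and Gm10359 had 245 and 0 counts and 235 and 0 counts, 82.9-fold and 79.5-fold lower against it. Folds against the floor take the nonzero count as exact, so they are not lower limits. The zinc finger family members Gm14440 and Gm14288 are near-identical copies of each other and had log2 ratios of 1.71 (95% interval 1.40 to 2.03) and -1.75 (95% interval -2.11 to -1.41); in the read-based tables they had 6 and 0 counts and 457 and 547 counts, the opposite direction for both. Gm28539, Gm6565 and the histone gene Hist1h4n had 1.53 (95% interval 1.28 to 1.79), -1.50 (95% interval -1.81 to -1.21) and -1.45 (95% interval -1.92 to -1.01). In the read-based tables Gm28539 had a log2 ratio of 0.78, Gm6565 and Gm5559 had 0 counts in both libraries, Gm10359 had 428 and 389 counts, Gm13394 had 0 and 12, and Hist1h4n had 0 and 31, the opposite direction. Of the 57 calls, 13 passed in the same direction in the read-based tables as well, among them Ttr, Rpl7a-ps11, Gm8226 and Gm14760. The protein-coding gene Slc47a1, named after its values were seen, is another of the 13, with 111 and 35 counts and 119 and 39 read-based counts.

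**Figure D4:**
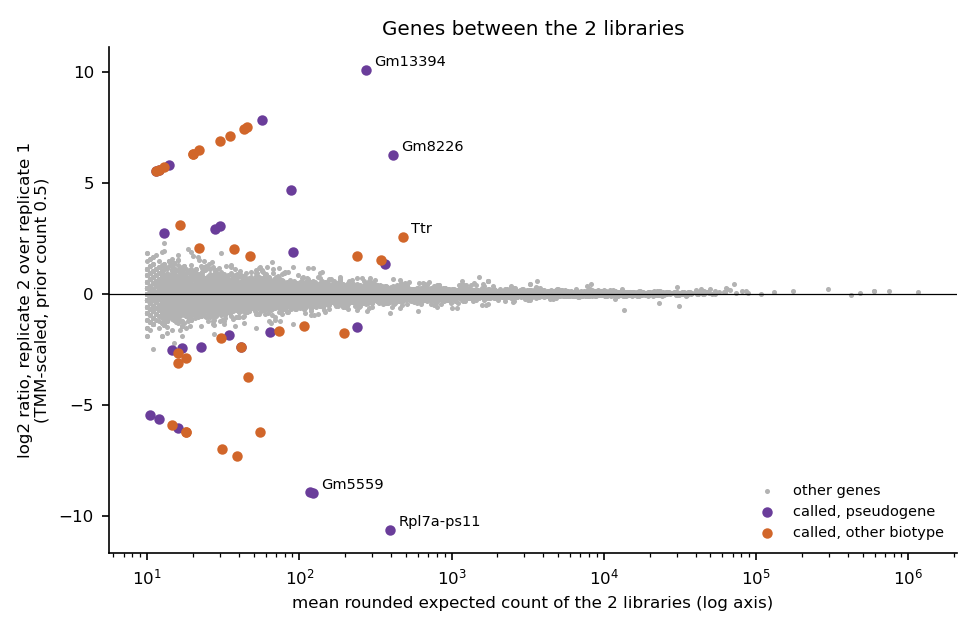
Log2 ratio of TMM-scaled counts, replicate 2 over replicate 1 (vertical axis), against the mean count of each gene (horizontal log axis) for 18562 genes; coloured points are the 57 genes whose 95% interval lies beyond 2-fold, and ratios of genes with 0 counts in 1 library depend on the prior count of 0.5. Ttr lies at 2.56, and the pseudogenes reach further in both directions.

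Several fixed gene lists differed as a group between the replicates. The fibroblast and meningeal list was lower in replicate 2, with a median log2 ratio of -0.41 (percentile 0 of 10000 random lists matched on size and mean count). Of its 10 tested members, 7 had intervals below 0, among them the transporter Slc22a6 -0.57 (-0.84 to -0.30), the growth factor Igf2 -0.52 (-0.62 to -0.42), the retinoic acid enzyme Aldh1a2 -0.51 (-0.78 to -0.24), Ogn -0.48 (-0.83 to -0.14) and the collagen Col3a1 -0.43 (-0.67 to -0.20), whereas Dcn had 0.34 (95% interval 0.12 to 0.56). The mural list had a median of -0.18 (percentile 0.07), with intervals below 0 for 5 of 10 members, among them Anpep -0.77 (-1.17 to -0.39), Acta2 -0.41 (-0.72 to -0.10) and Vtn -0.20 (-0.33 to -0.077). Ratios were above 0 for 3 mural members, among them Rgs5 0.078 (-0.026 to 0.18) and Kcnj8 0.21 (-0.38 to 0.81), none with an interval above 0. The endothelial list stayed within the random range at -0.0097 (percentile 46.6). The striatal list had a median of -0.30 (percentile 0), and all 11 tested members were lower in replicate 2, 10 with an interval below 0. The dopamine receptors had Drd2 -0.61 (-0.85 to -0.37) and Drd1 -0.45 (-0.59 to -0.31), the G-protein regulator Rgs9 -0.42 (-0.55 to -0.30), Gpr6 -0.39 (-0.78 to -0.0079) and Penk -0.32 (-0.41 to -0.24). The neuropeptide list, which shares Penk and Tac1 with the striatal list, had a median of -0.10 (percentile 0.29), with intervals below 0 for 3 and above 0 for 1 of 12 members, Nts -0.39 (-0.74 to -0.050) and Crh -0.35 (-0.66 to -0.034).

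Immediate early genes were lower in replicate 2, with a median of -0.23 (percentile 0). All 12 members had ratios below 0 and 9 had intervals below 0, with Fos -0.46 (-0.56 to -0.36), Junb -0.32 (-0.40 to -0.24), Npas4 -0.27 (-0.39 to -0.15), Egr4 -0.27 (-0.36 to -0.18) and Egr1 -0.24 (-0.27 to -0.20), while Arc -0.015 (-0.049 to 0.019) held 0 in its interval. The later activity-regulated list stayed inside the random range at 0.014. The clock list had a median of -0.047 (percentile 1.25), with intervals below 0 for 3 of 14 members, Dbp -0.26 (-0.39 to -0.13), Arntl -0.17 (-0.28 to -0.064) and Per1 -0.12 (-0.17 to -0.064); in the read-based tables its median of -0.033 lay inside the random range. The heat shock list was higher, with a median of 0.11 (percentile 99.9) and intervals above 0 for 5 of 9 members, among them the inducible Hspa1b 0.62 (0.43 to 0.82) and Hspa1a 0.23 (0.029 to 0.43), while Hspb1 0.28 (-0.084 to 0.64) held 0 in its interval.

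Oligodendrocyte, precursor and astrocyte lists were slightly higher in replicate 2, and the microglial list stayed inside the random range at 0.010 (percentile 64.8). The oligodendrocyte list had a median of 0.15 (percentile 99.99), with intervals above 0 for 8 of 12 members, such as Ermn 0.28 (0.10 to 0.47), Mobp 0.21 (0.15 to 0.28) and Mbp 0.21 (0.17 to 0.24), while the interval of Opalin -0.31 (-0.70 to 0.076) held 0. The precursor list had 0.095 (percentile 99.3), with intervals above 0 for 4 of 10 members, Enpp6 0.51 (0.081 to 0.94), Gpr17 0.19 (0.075 to 0.30) and Vcan 0.18 (0.037 to 0.32), and the astrocyte list 0.065 (percentile 99.3), with 6 of 12, among them Slc1a2 0.067 (0.056 to 0.078), S100b 0.10 (0.011 to 0.19) and Slc1a3 0.080 (0.040 to 0.12). The postsynaptic list had 0.063 (percentile 98.8), with 9 of 12, among them Shank1 0.13 (0.11 to 0.14), Shank2 0.13 (0.091 to 0.17) and Dlgap3 0.082 (0.047 to 0.12). Red blood cell genes were higher, with a median of 0.41 (percentile 100) and intervals above 0 for 3 of 5 members, Hba-a1 0.46 (0.36 to 0.57), Hba-a2 0.42 (0.30 to 0.54) and Hbb-bs 0.41 (0.30 to 0.51). All 6 tested choroid plexus genes were higher, with a median of 0.37 (percentile 99.8), but only Ttr and Prlr 0.74 (0.37 to 1.11) had intervals above 0; the median was 0.74 over the 3 members with a mean count of at least 100. Olfactory bulb genes went both ways, with a median of 0.44 (percentile 99.96), Doc2g 0.62 (0.072 to 1.19) and Calb2 0.44 (0.20 to 0.69) above 0 and Trh -0.54 (-0.92 to -0.16) below it; over the 3 members with a mean count of at least 100 the median was -0.12, the opposite direction.

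Mitochondrial mRNAs were higher in replicate 2, with a median of 0.19 (percentile 100) and intervals above 0 for 10 of 13 members, among them mt-Atp8 0.58 (0.52 to 0.65), mt-Nd4l 0.37 (0.33 to 0.42) and mt-Nd2 0.29 (0.27 to 0.31). mt-Atp6 -0.56 (-0.59 to -0.54) and mt-Co3 -0.41 (-0.44 to -0.39) went the other way. Both have a near-identical pseudogene on chromosome 1, and the summed counts of gene and pseudogene had log2 ratios of 0.13 with Gm10925 and 0.10 with Gm28437. In the read-based tables the list had a median of 0.19 over 11 members, but single genes differed from the values above. There mt-Atp6 had 0.013, mt-Co3 0.23 and mt-Nd2 0.28. mt-Nd3, named after its values were seen, had 0.22 in the alignment-based and -1.02 in the read-based tables, the opposite direction. mt-Atp8 had 0 read-based counts in both libraries and mt-Nd4l 11 and 5, so their higher values rest on the alignment-based tables alone.

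Of 39 lists with a ratio, 9 lay above and 6 below the central 95% of random lists, against 1.95 by chance if list members varied independently, which genes of 1 cell type do not. The other 24 lists lay inside, with medians from -0.090 for interferon-stimulated genes to 0.080 for hippocampal genes. The glucocorticoid list, inside at 0.055 (percentile 97.2), lay above the range in the read-based tables, at 0.11 (percentile 99.99). Intervals that excluded equality were found for 15.1% of all 18562 genes and also in lists inside the range, such as 5 of 12 pan-neuronal and 5 of 11 excitatory members above 0, so member counts alone do not set a list apart. The pan-neuronal, excitatory, inhibitory and microglial lists had 0.011, 0.033, -0.0053 and 0.010. The layer lists had -0.016 for layer 2/3, -0.053 for layer 4, -0.020 for layer 5 and -0.057 for layer 6. The median over all genes with a mean count of at least 10 was -0.0011.

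**Figure D5:**
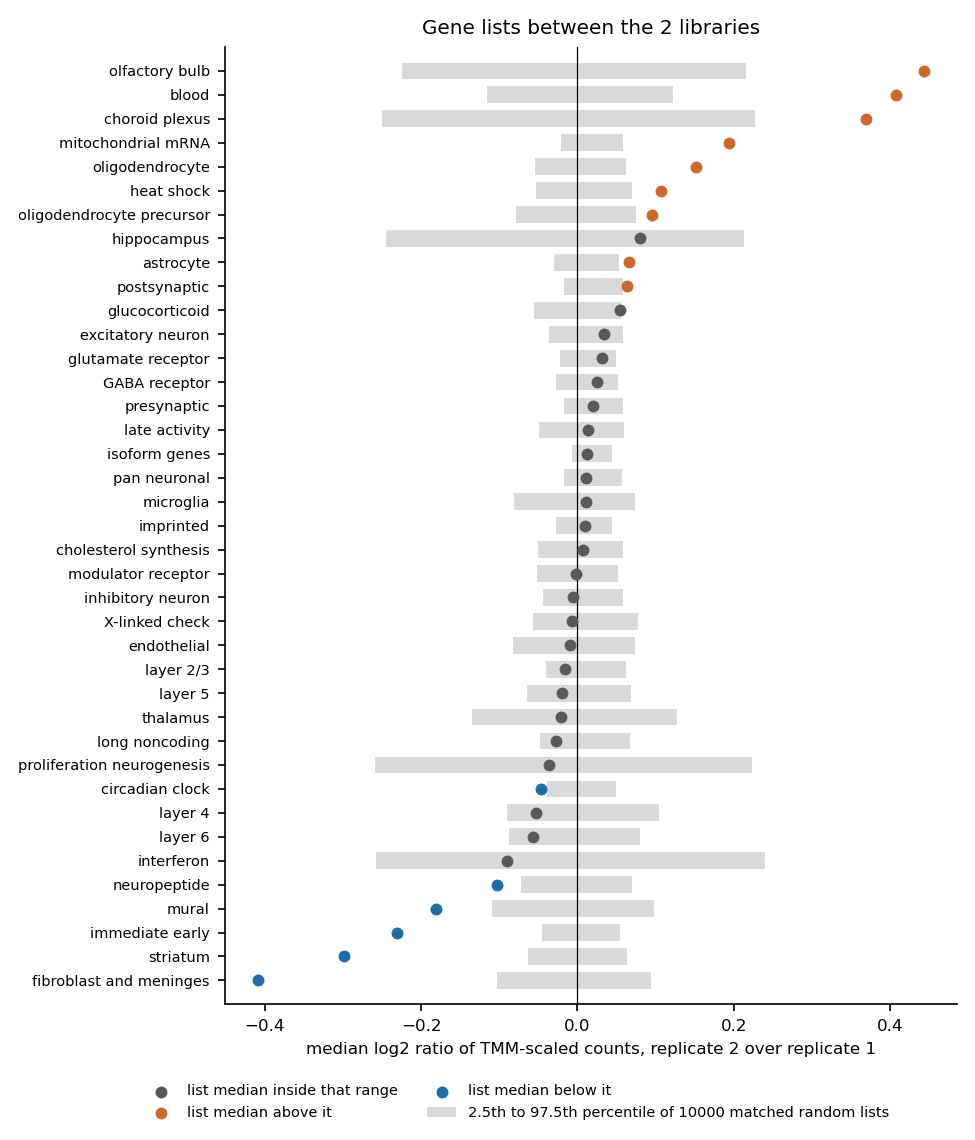
Median log2 ratio, replicate 2 over replicate 1 (horizontal axis), of 39 gene lists; grey bars span the central 95% of 10000 matched random lists, and coloured points are list medians outside their bar. The fibroblast and meningeal list is lowest at -0.41 and the olfactory bulb list highest at 0.44.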

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

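The 26248 transfer RNA features of the alignment-based gene table, which no result above uses, held 4.91 expected counts in replicate 1 and 4 in replicate 2. Both sums lie above the 3 counts that a sum of 0 allows, in a series without control samples. The counts were spread over 5 features in replicate 1 and 3 in replicate 2, and 26185 of the features have an effective length of 0 in the tables. The limit was applied to the sum, so these values show no signal on any single feature. No explanation was tested.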

How the results depend on the processing

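The restriction to protein-coding genes, the TPM over nuclear protein-coding genes, the count of calls shared by both quantifications and the sum of mitochondrial mRNAs with their pseudogenes were chosen after seeing the data. No paired analysis was possible because the series has 1 group. Detected genes numbered 10842 to 17581 over the settings tried, and 15726 to 15910 with 1 replicate left out. Spearman's rho fell to 0.956 when all genes above 0 in either library entered, which adds genes near the floor by construction. The common coefficient of variation ranged from 3.46% to 4.23%. The count of called genes was 57 (29 higher and 28 lower) and between 55 and 57 under the other scalings. It was 86 (45 higher and 41 lower) without a count filter, 12 (6 higher and 6 lower) at a mean count of at least 100, 89 (46 higher and 43 lower) beyond 1.5-fold, 28 (13 higher and 15 lower) among protein-coding genes and 13 (8 higher and 5 lower) in both quantifications; these settings test more or fewer genes or ask for less or more by construction.

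Median TPM of the cell class lists depends on what TPM is divided over, by construction. Without mitochondrial genes, spike-ins and ribosomal RNA the medians were 261 (pan-neuronal), 57.6 (excitatory), 46.6 (inhibitory), 57.7 (astrocyte), 31.4 (oligodendrocyte), 8.12 (precursor), 18.6 (microglial) and 9.72 (endothelial). Over nuclear protein-coding genes they were 519 (pan-neuronal), 115 (excitatory), 92.7 (inhibitory), 115 (astrocyte), 62.6 (oligodendrocyte), 16.2 (precursor), 36.9 (microglial), 19.3 (endothelial) and 8.98 (mural). In the read-based tables they were 345 (pan-neuronal), 117 (excitatory), 64.5 (inhibitory), 85 (astrocyte), 44 (oligodendrocyte), 10.3 (precursor), 24.6 (microglial), 16.7 (endothelial) and 5.13 (mural); the cause was not tested. The order of the 9 lists changed only by the swap of the astrocyte and excitatory lists, in the read-based tables, with the mean of log2(TPM + 1) and in replicate 1 alone. As shares of expected counts instead of TPM, nuclear protein-coding genes took 80.7%, mitochondrial mRNAs 1.56% (and 4.49% of TPM when summed with 4 pseudogenes), mitochondrial ribosomal RNA 5.17%, long intergenic RNAs 5.16%, the class of 7SL and 7SK 4.69%, spike-ins 0.367% and the 10 highest genes 14.8%, since counts are not divided by length.

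DESeq2 size factors and total count scaling shift all log2 ratios by 1 amount each (-0.0011 and 0.029 in library size), so they cannot move a list's percentile and test only the sign of its median. Of the 15 lists outside the random range, 14 stayed outside in the same direction in the read-based tables, where the clock list had -0.033 and the glucocorticoid list came to lie above the range at 0.11; the cause was not tested. At a mean count of at least 100, 14 stayed, and the olfactory bulb list turned to -0.12 with 3 members left. The leading transcript was the same in both libraries for 27 of 28 genes in the read-based tables, and in both quantifications for 24 to 25 genes with 1 replicate left out.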

Other observations

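Genes of the X chromosome and of autosomes were set side by side. Of 948 protein-coding genes on X, 428 (45.1%) reached 1 TPM in both libraries, against 12506 of 20807 (60.1%) on autosomes. Among detected genes the median level was 14.9 and 14.1 TPM on X and 16.6 and 15.6 TPM on autosomes in replicates 1 and 2. None of 183 protein-coding genes on Y reached that level.

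Peptide hormones of the hypothalamus had few counts in both libraries; they and the genes that follow were chosen after their values were seen. Avp, the vasopressin precursor, had 45 and 102 counts in replicates 1 and 2, a log2 ratio of 1.15 (95% interval 0.64 to 1.70), and the oxytocin precursor Oxt had 1 and 18 counts. Hcrt had 0 and 2 counts, Pmch 4 and 5 and Pomc 27 and 23, and the pituitary hormones Gh and Prl had 0 counts in both libraries. The prostaglandin D synthase gene Ptgds, made by meningeal cells and oligodendrocytes, had 1219.6 TPM in replicate 1 and 698 TPM in replicate 2, a log2 ratio of -0.73 (95% interval -0.76 to -0.69). The proteoglycan gene Fmod had -0.78 (95% interval -0.95 to -0.61), the transporter gene Slc13a4 -0.88 (95% interval -1.10 to -0.67), Islr -0.77 (95% interval -1.03 to -0.52) and Slc47a1 -1.67 (95% interval -2.28 to -1.13).

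The tests on short RNAs and on near-identical copies and the size of the GC and length trend were chosen only after the result was seen, and those on a second set of marker genes and on GC content were written down first.

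Short RNAs that led the alignment-based tables were almost missing from the read-based ones. All 72 genes (100%) with a longest transcript under 340 bases and a mean count of at least 100 kept under 5% of their count. Of genes of 680 bases or more, 28 of 12580 (0.223%) did so. Between these groups, from 340 to under 680 bases, it was 53 of 183 genes (29%), so the loss did not stop at 340 bases. A loss confined to small noncoding classes, whatever their length, is argued against by the protein-coding genes under 340 bases. All 4, 100%, were lost as well: Snurf, mt-Atp8, mt-Nd4l and Hist1h4k, named after their values were seen. The count of Snurf is uncertain, and mt-Nd4l has a near-identical copy, Gm10222, in the annotation. Whether shared sequence lowered the read-based counts of these 4 genes was not tested. Nor can 4 genes show whether class also played a part for the other 68 genes under 340 bases. A length limit of the read-based quantification, near its fragment length, is therefore a candidate explanation for the genes under 340 bases. A sharp limit at 340 bases does not cover the 53 genes lost above it, and the cause of their loss was not tested. No biological explanation was tested, since both tables come from the same libraries.

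Most genes called different between the libraries at a mean count of at least 100 may reflect reads assigned to different near-identical copies. Of the 11 called genes with such a copy, 7 had a summed count over gene and copies that differed by less than 50% of the difference of the gene alone. The 11 are not separate cases, since some called genes are copies of each other: Gm14440 and Gm14288, Rpl7a-ps11 and Gm8226, and those of Gapdh. Called copies that moved in opposite directions cancel in their shared sum. Rpl7a-ps11, Gm8226 and their copies summed to 3158 and 3244 counts, and Hist1h4n with Hist1h4m to 834 and 841. Of the other 4, Gm6565 lay at 50.1%, but with its copies it summed to 1803 and 1714 counts, a log2 ratio of -0.094 against -1.50 alone. Gm14760, Gm5559 and Gm10359 lay at 64.3%, 82.1% and 85.6%. Their Gapdh family, which Gm13394 shares at 37.8%, summed to 15690 and 15714 counts around Gm14760, a log2 ratio of -0.019. In the read-based tables Gapdh alone had 24562 and 24989 counts, more than this sum. The Gapdh sum may therefore miss reads of the family, and it cannot tell reads moved between copies from reads left out. Reads moved between copies stay open for these 4 as well. Ttr has no such copy in the annotation, and no biological explanation was tested for these genes.

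Striatal and fibroblast lists were lower in replicate 2. A trend of the ratio with GC content or transcript length is argued against, because the medians after its removal were -0.30 for the striatal and -0.42 for the fibroblast list, against -0.30 and -0.41 before, and because the trend was small: Spearman's rho of the ratio across genes was 0.044 with GC content and 0.031 with length, and the part removed lay between -0.055 and 0.13 for all 18550 genes, short of either median. A smaller share of striatal tissue stays open, since a second list of 18 striatal genes had a median of -0.091 (percentile 0.32), with 13 members lower, 7 intervals below 0 and 1 above it, that of Scn4b (0.13). A smaller share of meningeal or vascular fibroblasts stays open as well, since a second list of 19 fibroblast genes had -0.28 (percentile 0), with 17 members lower, 0 intervals above 0 and 7 below it, those of Tbx18 (-0.47), Gjb2 (-0.46) and Col5a1 (-0.44) among them, all named after their values were seen. With 1 library per replicate, a difference in dissection and one between animals cannot be separated here, and no biological explanation was tested.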
